A study of Homo sapiens with 6 samples.

How the data were processed

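RNA was measured by sequencing in 6 libraries, with 1 library per group. Of these, 5 came from H1, an established human embryonic stem cell line: undifferentiated cells (day 0), cells at days 2, 4 and 8 of a mesodermal induction with basic FGF, VEGF and BMP4, and endothelial cells derived from H1. The sixth was from human umbilical vein endothelial cells (HUVEC), a primary endothelial culture. Per the labels' protocols, ribosomal RNA was removed from DNase-treated total RNA and strand-specific paired-end libraries were made. The endothelial cultures were grown on collagen I in endothelial media, and the day of differentiation of the H1-derived endothelial cells was not given in the sources used here.

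The deposited table gives RPKM per gene (reads per kilobase of gene length, scaled to the reads of the library), per the file headers. The submitters' processing notes name STAR 2.2.0c, HOMER and the hg19 genome, with no role or order. The length given with the deposited RPKM values is the gene's whole genomic span, introns included, so a long gene with short exons has a low RPKM. Whether reads in introns were counted, how reads with several matches were handled and which annotation release was used are not given in the sources used here. The deposited values have 3 decimals. Gene names, types and 1-based hg19 coordinates were used as the table gives them.

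After removal of Y-linked genes, XIST and TSIX, 55169 genes were used, 19998 of them protein-coding and 12750 long non-coding RNAs (lncRNAs, non-coding types with a span of at least 200 bp). The low values of genes spanning 100 to 600 bp rose in whole multiples of 1 read, which gave each library's depth: 154.7, 136.3, 157.9 and 161.1 M reads at days 0, 2, 4 and 8, 130.8 M in the library labelled H1-derived endothelial cells and 163.1 M in HUVEC. At these depths 100% of the 2438 to 3677 low values tested per library lay within 0.1 of a whole read. Reads per gene were recovered from these depths and used for scaling factors, simulations and counting intervals, the last being exact 95% intervals of a ratio of 2 Poisson counts (conditional binomial, Clopper-Pearson). They cover counting error only.

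With 1 library per group no test between groups was possible, and none of the differences has a replicate check. The main description used the RPKM values as deposited and a rule of size: a gene was higher or lower when its log2 ratio of (RPKM + 0.5) was at least 1 in size, with 1 RPKM or more in the higher library. This scale understates the change of low genes. The 6 comparisons made this way were day 2 against day 0, day 4 against day 2, day 8 against day 4, and the library labelled H1-derived endothelial cells against day 8, day 0 and HUVEC. The 37 gene lists of cell types, pathways and controls, written before the data were examined, held 685 gene symbols, of which 8 were not matched and are not analysed here, PECAM1 among them. Some genes stand in several lists. A list's median was set beside 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Lists with under 3 members at 1 RPKM were not placed this way. A list member was counted where either library reached 1 RPKM. A list near 0 in 1 library is thus counted mainly through members high in the other, which favours that direction. A gene was called stage-restricted when its level in 1 of the 5 H1 libraries was at least 4-fold above each of the others on the same scale. Libraries were compared by correlation across genes at 1 RPKM or more in at least 1 library, and genes are not replicates.

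The genes named in the text followed a rule fixed before the data were examined. It took, in each comparison, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those at 5 RPKM or more, the 4 lncRNAs with the largest rise and the 4 with the largest fall among those at 2 RPKM or more, up to 4 members per gene list with the largest change, any known lncRNA, and a fixed set of marker genes in every library. Mitochondrial genes, ribosomal and small RNAs, pseudogenes, readthrough and histone genes, HLA genes and genes with common null alleles were not named under it. Other genes named in the text, such as the remaining members of small counts, were chosen after their values were seen. From this rule 538 of 723 gene and comparison pairs passed the size rule, each with a counting interval that lay wholly beyond a 2-fold difference. Genes that share a strand and a place with another gene may hold each other's reads, and such overlaps are stated for the genes described in full.

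The alternatives, changed separately, were TMM-like factors, median-of-ratios size factors, a library total over protein-coding genes, pseudocounts of 0.1 and 1, no minimum level or a minimum of 5 RPKM, a 4-fold threshold, and for stage restriction a 2-fold threshold. Added after the data were seen were reads scaled to the library alone in place of RPKM, stage restriction without the library labelled H1-derived endothelial cells, and list values for HUVEC against day 8. The rule of size was tested on reads simulated for all 55169 genes in each comparison, with 200 genes changed. The changed genes were drawn from those with a mean of 2 RPKM or more over the 2 libraries. Recovery of changes in lower genes was not simulated. In each of the 6 comparisons it recovered 50 of 50 genes changed 3-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, and called 0 or 1 of 50 changed 1.5-fold. Among unchanged simulated genes it called 3 at day 2 against day 0, 2 at day 4 against day 2, 3 at day 8 against day 4, and 0, 9 and 4 for the library labelled H1-derived endothelial cells against day 8, day 0 and HUVEC. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.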

Results

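Total RNA without ribosomal RNA was profiled along the differentiation of H1 human embryonic stem cells towards endothelium and in HUVEC. The course held undifferentiated cells (day 0), days 2, 4 and 8 of mesodermal induction, and endothelial cells derived from H1, with 1 library each, so that none of the differences below has a replicate check. Depth was 130.8 to 163.1 M reads per library. Between 6421 genes (day 2) and 7587 genes (day 0) reached 1 RPKM. The reads of all gene rows added up to 84.1% of the library at day 2 and 91.4% to 97.7% in the other libraries. A read in overlapping genes may enter this sum more than once. Mitochondrial ribosomal RNA took 0.393% of reads at day 0, 1.77% at day 2, 0.0625% at day 4 and 0.70% at day 8, 0.146% in the library labelled H1-derived endothelial cells and 0.593% in HUVEC. RNA28S5, a row named for 28S ribosomal RNA, stood at 4651, 497, 14422 and 6973 RPKM at days 0, 2, 4 and 8. It stood at 18538 RPKM in the library labelled H1-derived endothelial cells and 1193 in HUVEC.

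Marker genes were read in every library as a check of the labels. POU5F1, a core pluripotency factor, stood at 6.21 RPKM at day 0, 5.24 at day 2, 2.85 at day 4 and 0.330 at day 8, was listed at 0 in the library labelled H1-derived endothelial cells and stood at 0.033 in HUVEC. NANOG followed with 2.06, 2.48, 1.55 and 0.123 RPKM at days 0, 2, 4 and 8, then 0.002 and 0.004. SOX2 fell along the course from 126 RPKM at day 0 to 1.19 at day 8. T (brachyury), MIXL1 and MESP1, transcription factors of early mesoderm, peaked at day 2 with 2.94, 7.58 and 2.55 RPKM, against 0.019, 0.034 and 0.029 at day 0. KDR, the main VEGF receptor, climbed from 2.32 RPKM at day 0 to 16.8 at day 8. CDH5, the cadherin of endothelial junctions, stood at 1.46 RPKM at day 8 and 17.7 in HUVEC. The endothelial glycoprotein gene VWF reached 10.6 RPKM in HUVEC and at most 0.082 in the H1 libraries.

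These checks went against 1 label. In the library labelled H1-derived endothelial cells KDR stood at 0.659 RPKM, CDH5 at 0.531 and VWF at 0.046, each below its HUVEC level, while the fibrillar collagen gene COL1A1 stood at 133 RPKM against 0.022 in HUVEC. Every direction below that involves this library is therefore given for the library labelled so, beside its fibroblast and mural genes.

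**Figure D1:**
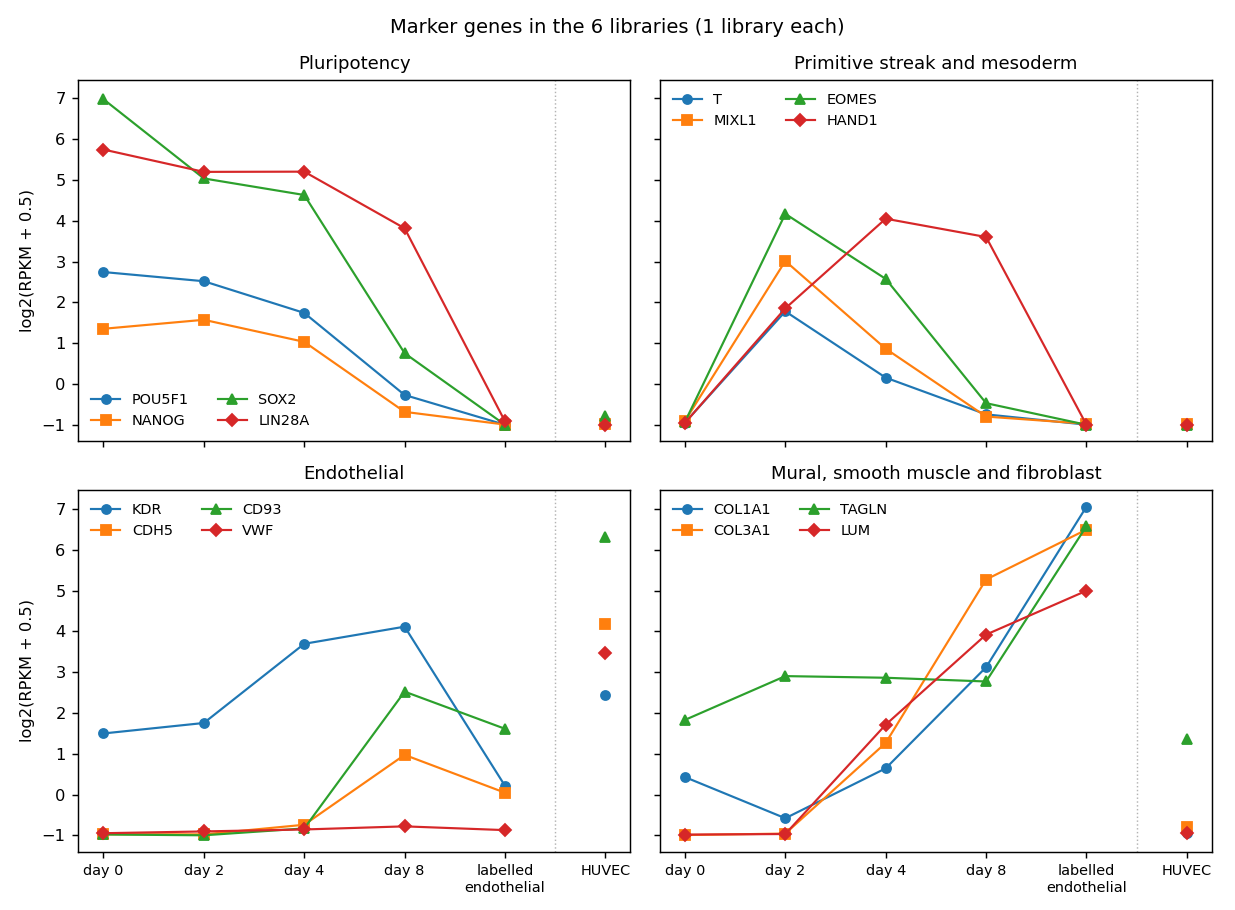
Levels of 16 marker genes as log2(RPKM + 0.5) on the vertical axis in each of the 6 libraries on the horizontal axis, in panels for pluripotency, early mesoderm, endothelial and fibroblast or mural genes; each point is 1 library, lines join the 5 H1 libraries and HUVEC stands apart. Pluripotency genes decline to the right, early mesoderm genes peak at day 2 or 4, and in the library labelled H1-derived endothelial cells KDR drops to 0.659 RPKM while COL1A1 reaches 133 RPKM.

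The first step, day 2 against day 0, addressed the entry of pluripotent cells into mesoderm. The primitive streak is the embryonic structure that gives rise to mesoderm and endoderm. Its list lay near 0 at day 0 (median 0.023 RPKM), so its members could pass the minimum level mainly by rising. Of its 20 genes 11 reached 1 RPKM at day 0 or 2, and all 11 rose. Their median log2 ratio was 2.61, above all 10000 random lists. EOMES, a T-box factor of the streak, rose from 0.025 to 17.5 RPKM (log2 ratio 5.10), MIXL1 by a log2 ratio of 3.92 and LHX1 from 0.050 to 6.61 RPKM (3.69). CER1, a secreted antagonist of NODAL, BMP and WNT signals, had the largest rise among genes at 5 RPKM or more, from 0.130 to 134 RPKM (7.74). The ratio of its RPKM values was 1031, with a 95% counting interval of 803 to 1356. CER1 (ENSG00000147869) lies on the minus strand of chromosome 9 from 14719722 to 14722715.

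Genes of several signalling pathways rose with them. All 12 members of the BMP target list at 1 RPKM or more, of 15, rose, with a median of 2.33. The BMP antagonist NOG went from 0.133 to 4.83 RPKM, the pseudoreceptor BAMBI from 1.32 to 14.5 and MSX1 from 0.048 to 3.82. In the NODAL pathway list 4 of 6 genes rose (NODAL, CER1, EOMES and GDF3) and TDGF1 and FOXH1 passed in neither direction, with NODAL itself at 2.13 RPKM against 0.106. Of the WNT target list 3 of 4 rose: SP5 (7.14 against 0.133 RPKM), DKK1 (2.84 against 0.076) and DKK4. In the FGF and ERK feedback list 1 of 8 genes rose (DUSP5) and 7 passed in neither direction, with a median of 0.57; 3 of 8 rose with TMM-like factors. All 5 lateral plate and cardiovascular genes at 1 RPKM or more, of 24 on the list, rose: BMP4, TBX3, APLNR, the apelin receptor (17.6 against 0.028 RPKM), HAND1 (3.12 against 0.016) and GATA6 (2.77 against 0.004). The 3 endoderm genes at 1 RPKM or more, of 17 on the list, rose as well: CER1, SOX17 (10.7 against 0.009 RPKM) and CXCR4. Outside these lists HAS2, which makes hyaluronan, rose from 0.118 to 13.8 RPKM.

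Of 19 pluripotency genes 6 fell, 1 rose and 12 passed in neither direction, and 4 fell with TMM-like factors. Their median was -0.52, or -0.35 relative to all genes, and 1 of 10000 random lists lay at or below it. DPPA4, among those that did not pass, stood at 19 RPKM against 38.5. SOX2, which lies inside SOX2-OT on the same strand, fell from 126 to 32.4 RPKM (-1.94), TERF1 from 10.5 to 3.23 and FOXD3 from 4.65 to 1.32, while the riser was GDF3 (1.1 against 0.286 RPKM). Among protein-coding genes at 5 RPKM or more the largest falls were those of IDO1, which degrades tryptophan (8.30 to 0.523 RPKM, -3.11), AASS, which degrades lysine (16.3 to 2.06, -2.72), and FGFBP3 (12 to 2.04, -2.30). In the hypoxia and glycolysis list 3 of 13 genes fell (VEGFA from 1.96 to 0.545 RPKM, BNIP3 and ENO2) and 0 rose; 2 fell with TMM-like factors. None of the 28 cell cycle genes passed the size rule; their median of -0.07 turned to 0.18 with TMM-like factors. Mitochondrially encoded genes stood higher, 5 of 12 by the size rule and 10 of 12 with TMM-like factors, beside the rise of mitochondrial ribosomal RNA to 1.77% of reads.

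Counted over 7925 genes at 1 RPKM or more, 165 were higher and 333 lower at day 2. Other scalings changed this balance: the median log2 ratio of all genes was -0.17 as deposited, 0.08 with TMM-like factors and 0.10 with median-of-ratios factors, and the share of higher among called genes went from 33.1% to 57.3% and 58.5% (45.5% with the protein-coding total). Protein-coding genes split into 120 higher and 137 lower, lncRNAs into 8 higher and 62 lower of 461. With TMM-like factors 9 of 422 lncRNAs were higher and 35 lower. The lncRNAs that fell included ESRG (18.1 to 6.91 RPKM), LINC00458 (5.20 to 1.44), RP11-267L5.1 (9.88 to 1.91) and RP11-44K6.2 (6.92 to 0.389), which lies inside IDO1 on the same strand and may share its reads. Those that rose included RP11-318L16.6 (0.372 to 4.41 RPKM) and RP11-586D19.2 (0.081 to 2.46). RP11-148B6.1, the row that holds the miR-302 cluster, stood at 50.4 RPKM against 70.9 and did not pass.

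**Figure D2:**
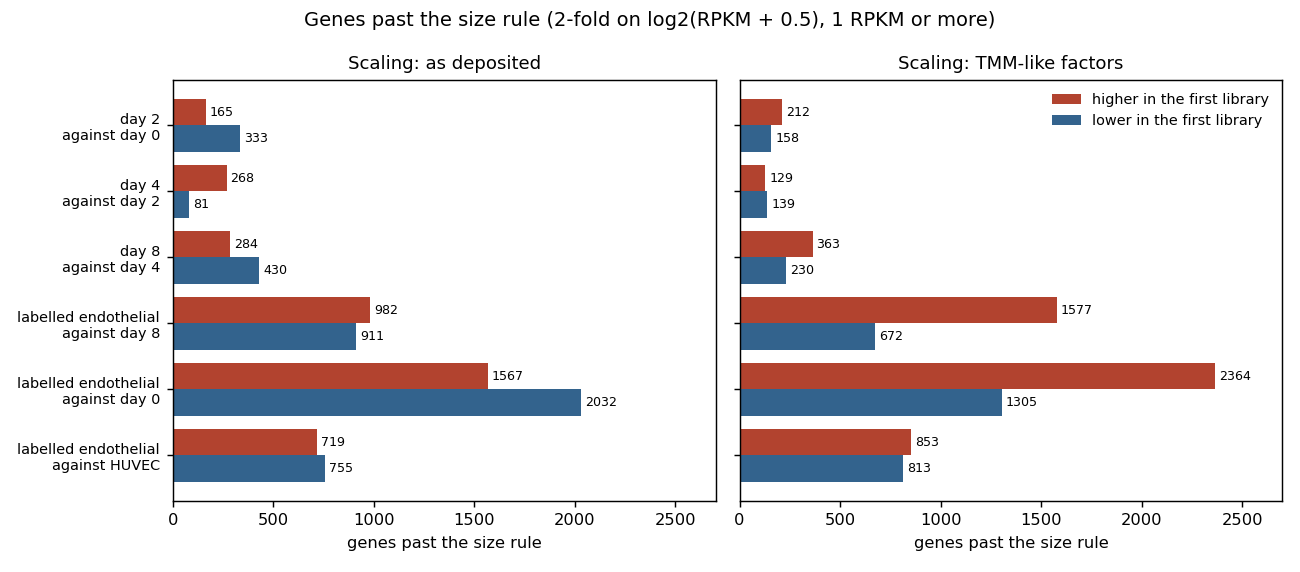
Numbers of genes (horizontal axis) past the size rule in each of the 6 comparisons (vertical axis), higher in red and lower in blue, for values as deposited (left) and with TMM-like factors (right); 1 library per group. At day 2 against day 0 the bars turn from 165 higher and 333 lower to 212 higher and 158 lower with TMM-like factors.

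Between days 2 and 4 the streak genes receded and lateral plate mesoderm genes rose. In the lateral plate and cardiovascular list 14 of 15 genes rose, with a median of 1.48, above all 10000 random lists (9 of 14 with TMM-like factors). HAND1 reached 16.1 RPKM against 3.12 (2.20), HAND2 1.84 against 0.031 (2.14) and NKX2-5, a heart field factor, 2.37 against 0.312 (1.82). Cardiomyocyte genes moved alongside, 4 of 5 rising: NKX2-5, MYL7, the cardiac actin gene ACTC1 (25.2 RPKM against 4.20) and TNNC1 (2.53 against 0.240). VIM, the mesenchymal intermediate filament gene, rose from 7.65 to 90.8 RPKM (3.49), and fibronectin (FN1) from 3.94 to 19.9 (2.20); 7 of 10 mesenchymal genes rose and 3 did not pass.

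Some early vascular genes rose at the same step. All 3 endothelial genes at 1 RPKM or more, of 34 on the list, passed in values as deposited, but only KDR with TMM-like factors. These factors divide day 4 levels by 1.22, which took TAL1 under the minimum level. KDR went from 2.87 to 12.5 RPKM (1.94), TAL1, a factor shared by blood and endothelium, from 0.007 to 1.18 (1.73), and FLT1, another VEGF receptor, from 0.690 to 2.26 (1.21), having stood at 1.60 at day 0. KDR lies on the minus strand of chromosome 4 from 55944644 to 55991756. Of 9 arterial genes 5 rose: EFNB2, GJA4, CXCR4, NRP1 and the NOTCH effector HEY1 (2.58 against 0.539 RPKM). EFNB2 and GJA4 did not pass with TMM-like factors, which left 3 of 7. GJA4, at 1.21 RPKM at day 4 as deposited, came under the minimum level with these factors. Of 10 fibroblast and mural genes 4 rose: COL1A1, RGS5, LUM (2.78 against 0.011 RPKM) and COL3A1 (1.90 against 0.015). With TMM-like factors 3 of 8 rose and 1 fell (THY1). COL1A1, at 1.06 RPKM at day 4 as deposited, came under the minimum level with these factors. Other large rises were those of TMEM88, an inhibitor of WNT signalling (7.71 against 0.284 RPKM), APOA1 (4.07 against 0.020) and HAPLN1 (9.83 against 1.11).

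In the streak list 7 of 12 genes fell, 1 rose (CDX2, 1.37 against 0.391 RPKM, a call not made with TMM-like factors) and 4 did not pass, with a median of -1.12. CER1 fell from 134 to 16.9 RPKM (-2.95), GSC from 2.63 to 0.145 (-2.28), MIXL1 from 7.58 to 1.32 (-2.15) and T from 2.94 to 0.614 (-1.63). Of 6 NODAL pathway genes 5 fell: NODAL, TDGF1, CER1, GDF3 and EOMES. Of 19 pluripotency genes 3 fell (SFRP2, TDGF1 and GDF3; 6 with TMM-like factors) and 16 did not pass, with a median of -0.54, below all 10000 random lists. Among those that did not pass, POU5F1 stood at 2.85 RPKM against 5.24, L1TD1 at 27.2 against 52.6 and LIN28A at 36.4 against 36.3. Among protein-coding genes at 5 RPKM or more the largest falls belonged to 6 long genes, including ANKRD30BL (156 to 3.01 RPKM, -5.48), HFM1 (76.5 to 1.25, -5.46) and PDE3A (41.3 to 0.849, -4.95), which moved with mitochondrial 16S ribosomal RNA (8248 to 321 RPKM). Mitochondrially encoded genes fell with them in 9 of 12 cases.

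Of 7768 genes 268 were higher and 81 lower at day 4. The median of all genes was 0.18 as deposited and -0.14 with TMM-like factors, and the share of higher among called genes went from 76.8% to 48.1% (49.4% with median-of-ratios factors, 66.2% with the protein-coding total). Of 398 lncRNAs 21 were higher and 7 lower (13 and 14 of 359 with TMM-like factors). H19, an imprinted lncRNA of growing fetal tissue, rose most (0.173 to 11.7 RPKM, 4.18), followed by AC093388.3 (0.108 to 2.11) and RP11-480G7.1 (0.257 to 2.66). MALAT1, a nuclear lncRNA, reached 230 RPKM against 75.6. ESRG fell again (6.91 to 2.60 RPKM).

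From day 4 to day 8 endothelial genes rose broadly. Of the 16 endothelial genes at 1 RPKM or more 14 rose, with a median of 1.55, above all 10000 random lists; KDR (16.8 against 12.5 RPKM) and TAL1 (1.40 against 1.18) did not pass. CD93, a receptor of endothelial cells, went from 0.062 to 5.25 RPKM (3.35), EGFL7, a secreted endothelial factor that hosts MIR126, from 0.937 to 8.65 (2.67), CLEC14A from 0.034 to 2.51 (2.49) and CDH5 from 0.098 to 1.46 (1.71). Arterial genes rose in 8 of 13 cases, with the NOTCH ligand DLL4 at 2.86 RPKM against 0.022, the connexin gene GJA5 at 5.51 against 0.443 and HEY1 at 12.3 against 2.58; SOX17 fell (3.16 against 11). The adhesion molecule E-selectin (SELE, 2.62 against 0.022 RPKM) and the chemokine CCL2 (17.0 against 0.743) also rose.

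Genes of other lineages rose beside them. Fibroblast and mural genes rose in 7 of 14 cases (median 1.00, none lower): COL3A1 from 1.90 to 38.1 RPKM (4.01), LUM from 2.78 to 14.6 (2.21) and COL1A1 from 1.06 to 8.20 (2.48). In the endoderm list 6 of 10 genes rose, including the apolipoprotein gene APOB (3.56 against 0.192 RPKM) and FGB, a fibrinogen chain (2.14 against 0.068), while CER1 and SOX17 fell. The HOXB cluster, whose genes pattern the body axis, rose in 5 of 6 measured genes: HOXB3, HOXB6, HOXB8, HOXB9 and HOXB4 (4.78 against 0.909 RPKM). HAND2, a heart and limb factor, rose from 1.84 to 18.4 RPKM, and the growth factor IGF2 from 0.225 to 7.88.

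Pluripotency genes fell here, 14 of 16 with 2 not passing (median -1.90; 13 with TMM-like factors). SOX2 dropped from 24.3 to 1.19 RPKM (-3.88), L1TD1 from 27.2 to 1.89 (-3.53), ZFP42 from 12.5 to 2.09 (-2.33) and the DNA methyltransferase gene DNMT3B from 8.80 to 1.65 (-2.12). RP11-148B6.1, which holds the miR-302 cluster, fell from 29.7 to 2.22 RPKM (-3.47). EOMES fell from 5.47 to 0.222 RPKM, with MIXL1, SP5 and LHX1 the other streak genes that fell (4 of 5), and TDGF1, CER1 and FOXH1 fell in the NODAL pathway list. The long genes ANKRD30BL, NOTCH2NL, HFM1 and SLCO5A1 rose again (52.4, 50.7, 19.8 and 13.8 RPKM at day 8), beside mitochondrial 16S ribosomal RNA at 3120 RPKM.

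Of 8315 genes 284 were higher and 430 lower at day 8. The median of all genes was -0.19 as deposited and 0.01 with TMM-like factors, and the share of higher among called genes went from 39.8% to 61.2% (55.6% with median-of-ratios factors). Of 446 lncRNAs 29 rose and 38 fell (37 and 25 of 401 with TMM-like factors). AC132217.4 rose most, from 1.94 to 82.1 RPKM (5.08). It lies on the minus strand of chromosome 11 from 2150351 to 2151194, inside the IGF2 span (2150342 to 2182439) on the same strand, so reads of IGF2 may be counted in it. H19 stood nearby on the same strand (2016406 to 2022700) and reached 136 RPKM (3.48). DNM3OS, the host of MIR199A2, rose from 0.082 to 3.94 RPKM.

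Moving from day 8 to the library labelled H1-derived endothelial cells, endothelial genes were lower. Of 16 endothelial genes 11 were lower, 0 higher and 5 passed in neither direction, with a median of -1.48, below all 10000 random lists. KDR stood at 0.659 RPKM against 16.8 (-3.90), EGFL7 at 1.02 against 8.65 (-2.59) and the fenestral protein gene PLVAP at 0.011 against 2.31 (-2.46), while CD93 (2.56 against 5.25), CLEC14A (4.25 against 2.51), CDH5, TIE1 and S1PR1 did not pass. Arterial genes were lower in 9 of 13 cases (HEY1 0.421 against 12.3 RPKM, GJA4 0.050 against 6.38, GJA5 0.036 against 5.51) and haemato-endothelial progenitor genes in 8 of 10; with TMM-like factors 8 of 13 arterial genes were lower. BMP targets were lower in 12 of 14 (10 with TMM-like factors), with SMAD6 at 0.114 RPKM against 8.53 and ID4 at 0.083 against 6.29.

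Fibroblast, smooth muscle and matrix genes were higher in the same library. In the fibroblast and mural list 12 of 16 genes were higher and 1 lower (RGS5, a pericyte gene, 0.145 against 5.15 RPKM), with a median of 1.49. COL1A1 stood at 133 RPKM against 8.20 (3.94), COL1A2 at 56.7 against 5.85 (3.17) and TAGLN, a smooth muscle actin-binding protein, at 95.1 against 6.33 (3.81). Of 17 matrix genes 12 were higher and 0 lower, with thrombospondin 1 (THBS1) at 261 RPKM against 3.38 (6.08). CTGF (121 against 2.46), the coagulation initiator F3 (28.1 against 0.513), INHBA (20.5 against 0.375) and the chemokine IL8 (10.3 against 0.023) were also higher. THBS1 was high in HUVEC too, at 758 RPKM, whereas COL1A1 was not (0.022).

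Proliferation genes were low. All 45 histone genes of the replication-dependent list were lower (median -3.40), and 44 with TMM-like factors. All rows with a HIST name, on the list or not, together took 0.139% of reads against 1.1%. Of 28 cell cycle genes 27 were lower (median -1.99), with the topoisomerase gene TOP2A at 0.996 RPKM against 12.4 and CDK1 at 0.289 against 5.28. In HUVEC 28 of 28 cell cycle genes (25 with TMM-like factors) and 43 of 45 histone genes (42) were lower than at day 8. Set against HUVEC directly, 2 histone genes were higher and 6 lower of 44 in the library labelled H1-derived endothelial cells. Of 11 genes of the CDK inhibitor and senescence list 8 were higher, among them CDKN2B (29.3 against 2.00 RPKM) and CDKN1A (27.8 against 4.14), and 2 were lower, CDKN1C and LMNB1. Among other genes, the imprinted lncRNA H19 stood at 0.160 RPKM against 136 (-7.69), and HAND1 (11.7 RPKM at day 8) was listed at 0. LIN28A (0.030 against 13.6 RPKM), APOA1 (0.010 against 11.1) and 8 of 9 endoderm genes were lower as well.

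Of 8388 genes 982 were higher and 911 lower in the library labelled H1-derived endothelial cells than at day 8. The median of all genes was 0.05 as deposited, 0.35 with TMM-like factors and 0.39 with median-of-ratios factors, and the share of higher among called genes went from 51.9% to 70.1% and 72.3%. Of 461 lncRNAs 64 were higher and 81 lower, a balance that turned with TMM-like factors (103 and 56 of 489). SFTA1P (4.05 against 0.003 RPKM), MIR31HG (4.99 against 0.225), MIR137HG (2.89 against 0.024) and AC005027.3 (9.80 against 0.189), which overlaps INHBA on the same strand, rose most. RP11-319F12.2 (7.38 RPKM at day 8) was listed at 0.

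Set against day 0, the same library covers the start and end of the course. All 18 pluripotency genes were lower (median -3.61): SOX2, at 126 RPKM at day 0, was listed at 0, LIN28A stood at 0.030 against 53.3 and DPPA4 at 0.078 against 38.5. All 28 cell cycle genes (median -2.45) and 45 of 45 histone genes (-3.53; 44 with TMM-like factors) were lower. The epithelial list split, with 9 of 12 genes lower, among them the claudin genes CLDN6 (0.008 against 5.48 RPKM) and CLDN7 (0.193 against 4.25), and 3 keratin genes higher, KRT18 at 274 RPKM against 20.1, KRT8 at 17.8 against 0.936 and KRT19.

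Matrix and mesenchymal genes were higher. All 10 mesenchymal genes (median 4.45), 13 of 15 fibroblast and mural genes (3.83) and 14 of 16 matrix genes (2.96) were higher, with COL3A1 at 89.7 RPKM against 0.002 (7.49), FN1 at 150 against 0.723 (6.95) and the small galectin gene LGALS1 at 159 against 0.311 (7.62). All 7 HOXB genes at 1 RPKM or more were higher, and 7 of 10 immediate early genes, led by the phosphatase gene DUSP1 (43.2 against 1.00 RPKM). All 4 endothelial activation genes at 1 RPKM or more, of 15 on the list, were higher too (ICAM1, IL8, CXCL1 and NFKBIA), with a median of 3.01. Against day 8 the same list split into 3 higher and 3 lower of 7 (median -0.20), and against HUVEC 7 of 9 were lower. Among endothelial genes 3 of 6 were higher, CLEC14A (4.25 against 0.023 RPKM), CD93 (2.56 against 0.007) and S1PR1 (2.54 against 0.208), and KDR was lower (0.659 against 2.32; -1.28), a call not made with TMM-like or median-of-ratios factors.

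The counts were 1567 higher and 2032 lower of 9267 genes. The median of all genes was -0.18 as deposited and 0.32 with TMM-like factors, and the share of higher among called genes went from 43.5% to 64.4% (65.2% with median-of-ratios factors). Of 575 lncRNAs 115 were higher and 218 lower, against 152 and 150 of 563 with TMM-like factors. The miR-302 host RP11-148B6.1 (70.9 RPKM at day 0) and CTD-2306M5.1 (17.9) were listed at 0, and ESRG (0.002 against 18.1) and RP11-1144P22.1 (0.001 against 20.9) were near it. NEAT1, a structural RNA of nuclear paraspeckles, stood at 40.2 RPKM against 0.919 (4.84) and RP11-524D16__A.3 at 26.4, being listed at 0 at day 0.

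Compared with HUVEC, the library labelled H1-derived endothelial cells had low endothelial genes. Of 29 genes on that list 28 were lower, 0 higher and 1 (FLT1, 2.12 against 1.32 RPKM) passed in neither direction, with a median of -2.76, below all 10000 random lists. VWF stood at 0.046 RPKM against 10.6 (-4.34), CDH5 at 0.531 against 17.7 (-4.14), CD93 at 2.56 against 79.6 (-4.71) and the multimerin gene MMRN1 at 0.231 against 37.5 (-5.70). All 11 haemato-endothelial genes, 5 of 8 arterial (NOTCH1, JAG2, SOX17, ACVRL1 and BMX), 4 of 5 venous (EPHB4, FLRT2, TEK and NR2F2) and 7 of 9 endothelial activation genes were lower; NOTCH1 and EPHB4 did not pass with TMM-like factors. The venous regulator NR2F2 stood at 1.45 RPKM against 8.40 and CCL2 at 0.10 against 58.1 (-6.61). The matrix inhibitor of calcification MGP (0.019 against 11 RPKM), the collagenase gene MMP1 (1.67 against 46.9) and APLN, the apelin ligand (0.128 against 12.6), were among the largest differences.

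Fibroblast and mural genes stood on the other side, 12 of 14 higher and 1 lower (RGS5), with a median of 2.79. COL1A1, on the minus strand of chromosome 17 from 48260650 to 48278993, stood at 133 RPKM against 0.022 (7.99), COL3A1 at 89.7 against 0.078 (7.29), LUM at 31.4 against 0.024 (5.93) and TAGLN at 95.1 against 2.07 (5.22). The 3 epithelial genes at 1 RPKM or more were higher, all of them keratin genes (KRT8, KRT18 and KRT19), as were 6 of 9 lateral plate genes, among them FOXF1 (11.9 against 0.963 RPKM) and TBX3 (4.62 against 0.095). IGFBP5 (75.9 against 0.025), WNT5A (27.1 against 0.047) and F3 (28.1 against 0.055) were further large differences. Matrix genes overall split into 7 higher and 6 lower of 20, and none of the 10 cell cycle genes at 1 RPKM or more passed.

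The counts were 719 higher and 755 lower of 8042 genes, and the share of higher among called genes was 48.8% as deposited, 51.2% with TMM-like factors, 51.3% with median-of-ratios factors and 53.6% with the protein-coding total. Of 440 lncRNAs 58 were higher and 83 lower. Higher were CTD-2001E22.2 (7.43 against 0.047 RPKM), RP11-46C20.1 (4.26 against 0.014) and AC132217.4 (73.0 against 1.64), the transcript inside IGF2. Lower were RP1-140K8.5 (0.409 against 16 RPKM), LINC00607 (0.111 against 7.23), RP3-523C21.1 (0.185 against 8.02), NEAT1 (40.2 against 129) and MEG3 (0.097 against 2.16).

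**Figure D3:**
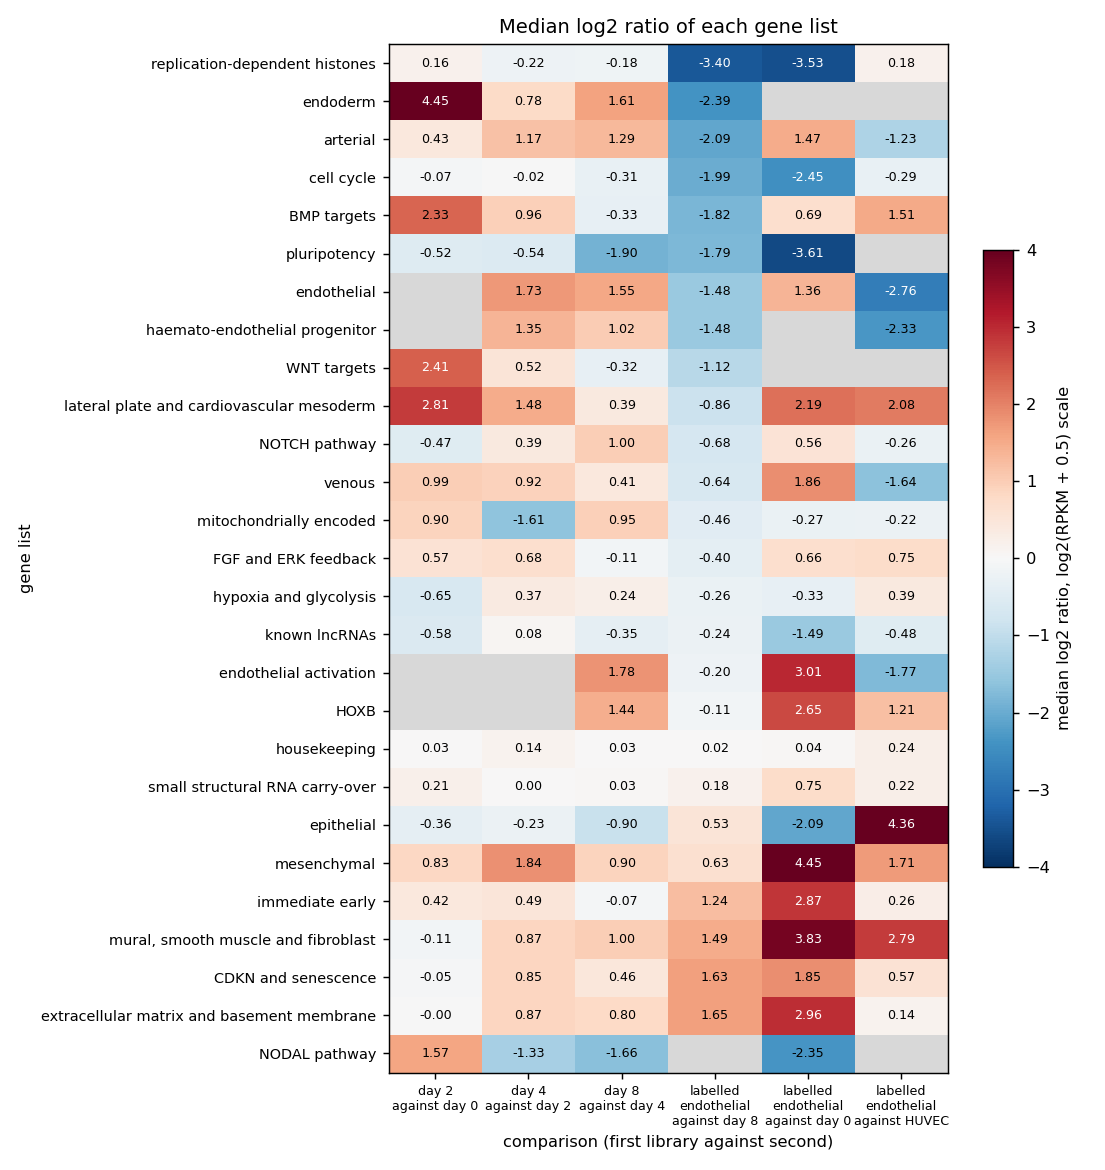
Median log2 ratio of 27 gene lists (vertical axis) in the 6 comparisons (horizontal axis), as colour from -4 to 4 and as printed values, over list members at 1 RPKM or more in values as deposited; grey marks fewer than 3 such members and each library is a single one. The endothelial list stands at 1.55 at day 8 against day 4 and at -1.48 and -2.76 in the library labelled H1-derived endothelial cells against day 8 and HUVEC, and small medians such as the cell cycle at day 2 (-0.07 as deposited, 0.18 with TMM-like factors) turn sign with scaling.

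Each library was then placed by its correlation with the others across 10725 genes, which are not independent replicates. Neighbouring days were close, with a Spearman correlation of 0.909 between days 0 and 2, 0.936 between days 2 and 4 and 0.862 between days 4 and 8. For the library labelled H1-derived endothelial cells the value was 0.750 with HUVEC, 0.711 with day 8 and 0.478 with day 0, so that HUVEC was nearest. HUVEC lay at 0.634 from day 8. This order is no check of the label, since 28 of 29 endothelial genes were lower in the library labelled H1-derived endothelial cells than in HUVEC. Both libraries also had low cell cycle genes, 27 and 28 of 28 being lower than at day 8.

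Stage restriction asked which genes mark a single point of the course. By the 4-fold rule 191 of 10069 genes were restricted to 1 of the 5 H1 libraries, whereas reads drawn with no difference between libraries gave 0. Day 0 held 7 such genes, day 2 held 5 (4 of them protein-coding), day 4 held 0, day 8 held 22 and the library labelled H1-derived endothelial cells 157. Without that library 60 genes were restricted, 46 of them to day 8. Day 0 was marked by IDO1, AASS and HES3, day 2 by CER1, GSC, DKK4 and MIXL1, and day 8 by CCL2, HAND2, GJA5, TMEM100 and H19.

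The series concerns lncRNAs, and their restriction was set beside that of protein-coding genes. Of 652 lncRNAs 15 (2.30%) were restricted, and of 6916 protein-coding genes 155 (2.24%). On the scale used, a gene with its highest level close to 1 RPKM cannot pass the rule, even if absent from the other libraries. The highest level lay between 1 and 2 RPKM for 339 of these lncRNAs and 3084 of these protein-coding genes. The low shares in that bin thus follow in part from the rule, and the near-equal totals alone cannot show equal restriction. Within bins of the highest level the shares were 0.295% for lncRNAs and 0.227% for protein-coding genes between 1 and 2 RPKM, 3.96% and 2.02% between 2 and 5, 4.76% and 5.83% between 5 and 20, and 7.41% and 10.9% at 20 or more, the last lncRNA bin resting on 2 of 27 genes. Of the 15 lncRNAs 12 marked the library labelled H1-derived endothelial cells, including SFTA1P, MIR137HG and CTD-2021J15.2.

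HOX genes, which record position along the body axis, were compared between HUVEC and the library labelled H1-derived endothelial cells. In the latter 4 of 7 HOXB genes were higher (HOXB2, HOXB6, HOXB8 and HOXB9) and 3 passed in neither direction. Of 6 HOXA genes HOXA13 was higher and 3 were lower (HOXA5, HOXA6 and HOXA9), and of 4 HOXD genes HOXD10 was higher and 3 were lower (HOXD1, HOXD4 and HOXD8). HOXB9 stood at 3.22 RPKM at day 8 and 4.06 in the library labelled H1-derived endothelial cells, against 0.069 in HUVEC and 0.002 at day 0, and HOXA13 at 2.55 and 1.60 against 0.007 and 0.001. HOXD8 (2.01 RPKM in HUVEC) and HOXA5 (2.79) stood at no more than 0.260 and 0.234 in the H1 libraries. Between day 8 and the library labelled H1-derived endothelial cells none of 7 HOXB genes passed the size rule; their median of -0.11 turned to 0.18 with TMM-like factors.

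**Figure D4:**
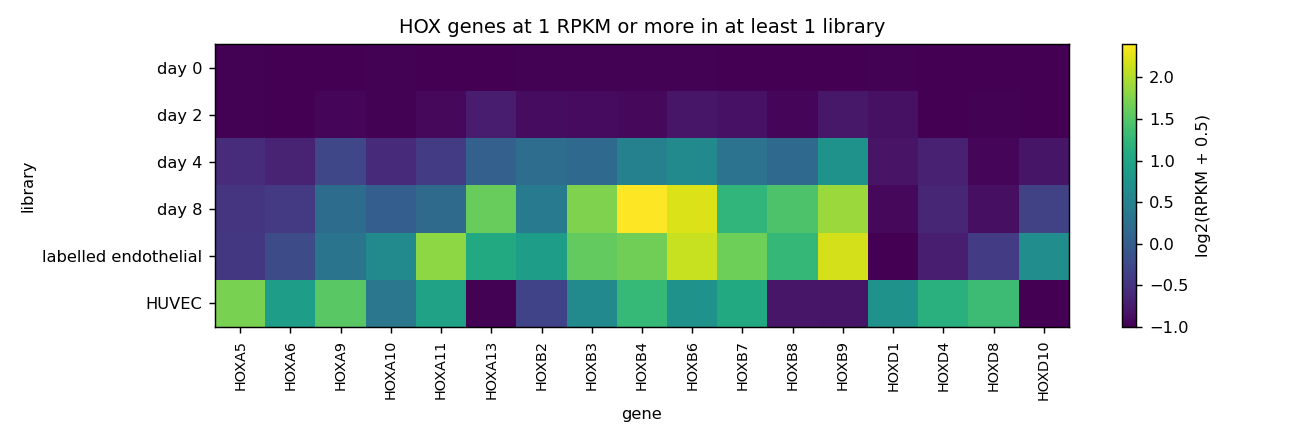
Levels of the 17 HOX genes at 1 RPKM or more in at least 1 library (horizontal axis) in the 6 libraries (vertical axis), as colour on the log2(RPKM + 0.5) scale, with 1 library per group. HOXB9 is at 4.06 RPKM in the library labelled H1-derived endothelial cells and 0.069 in HUVEC, and HOXD8 at 0.260 and 2.01.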

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

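Of the settings tried, reads scaled to the library alone and stage restriction without the library labelled H1-derived endothelial cells were added after the results were seen. Of 162 list medians, 71 were past 1 in size as reported, against 78 of 160 with TMM-like factors (66 in common, 3 now under 1), 79 with median-of-ratios size factors (67 in common), 75 with the protein-coding total (71 in common), 84 with a pseudocount of 0.1 (71 in common) and 59 with a pseudocount of 1 (12 now under 1). With no minimum level 30 gene list medians were past 1, as members near 0 enter the lists. A minimum level of 5 left 48 of 101 past 1 and reversed 2: the endoderm list at day 8 against day 4 (median -1.65, 1.61 as reported) and the epithelial list in the library labelled H1-derived endothelial cells against day 0 (2.68, -2.09 as reported), since few members are left. Of 723 named genes and comparisons 538 passed the size rule as reported, 520 with TMM-like factors, 469 with a pseudocount of 1 and 286 at a minimum level of 5, none of them reversed. Adding up several entries of a gene could not be tried, as each gene identifier has 1 entry. The causes of the shifts below were not tested, except that a threshold or a pseudocount moves counts by construction.

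With TMM-like factors the genes lower at day 2 against day 0 numbered 158, those higher and lower at day 4 against day 2 were 129 and 139, and those lower at day 8 against day 4 were 230. For the library labelled H1-derived endothelial cells 1577 genes were higher than at day 8, and 2364 were higher and 1305 lower than at day 0. With median-of-ratios size factors the same counts were 156, then 133 and 136, then 264, then 1658, then 2405 and 1285, and 287 genes were stage-restricted.

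With a pseudocount of 0.1 the count was 602 lower at day 2, 431 higher at day 4, 429 higher and 662 lower at day 8, each against the day before it, and the count of stage-restricted genes was 374. With a pseudocount of 1 it was 161 lower at day 2, 153 higher at day 4, 179 higher and 278 lower at day 8, 603 lower in the library labelled H1-derived endothelial cells than at day 8, and 114 stage-restricted.

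With a minimum level of 5 RPKM the genes higher and lower numbered 59 and 93 at day 2, 75 and 48 at day 4, and 85 and 216 at day 8. For the library labelled H1-derived endothelial cells they numbered 457 and 239 against day 8, 590 and 618 against day 0, and 282 and 222 against HUVEC, with 119 stage-restricted genes. With a fold threshold of 4 they were, in the same order, 52 and 19, 42 and 20, 61 and 38, 216 and 221, 524 and 560, and 230 and 234.

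With reads scaled to the library alone in place of RPKM the counts were 741 and 2278, 1685 and 207, 1286 and 1748, 2127 and 4926, 3375 and 6488, and 2180 and 2466, with 767 stage-restricted genes. Long genes with low RPKM pass the minimum level on this scale. A 2-fold threshold gave 1057 stage-restricted genes, and 60 were restricted without the library labelled H1-derived endothelial cells. The correlation of that library with HUVEC (0.750 as reported) was 0.736 over genes at 5 RPKM or more, 0.735 over protein-coding genes and 0.856 as a Pearson correlation of log2 values; under all 4 measures HUVEC was its nearest library.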

Other observations

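The lncRNAs named in this paragraph were picked after their values were seen. NEAT1 stood at 0.919 RPKM at day 0, 0.774 at day 2, 3.85 at day 4 and 14.4 at day 8, then at 40.2 in the library labelled H1-derived endothelial cells and 129 in HUVEC. MALAT1, another abundant nuclear RNA, stood at 133, 75.6, 230, 498, 694 and 976 RPKM in the same order. MIR17HG, the host of the miR-17 cluster, fell from 7.70 RPKM at day 4 to 3.21 at day 8, a call not made with TMM-like factors, and DANCR from 6.81 to 2.29. TUG1 stood between 9.03 and 11.4 RPKM in all 6 libraries. Of 20 known lncRNAs 6 were higher and 11 lower in the library labelled H1-derived endothelial cells than at day 0, with a median of -1.49, below all 10000 random lists. Their median also lay below all of them at day 2 against day 0 (-0.58) and above 0.34% of them against HUVEC. It lay above 18.6% at day 4 against day 2, 19.8% at day 8 against day 4 and 11.5% in the library labelled H1-derived endothelial cells against day 8. The random lists were drawn from genes of all types, so these places may also hold the shift of lncRNAs as a class. The median of all lncRNAs was -0.42 at day 2 against day 0, beside -0.17 for all genes. In the library labelled H1-derived endothelial cells it was -0.59 beside -0.18 against day 0, and -0.11 beside 0.09 against HUVEC.

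In the library labelled H1-derived endothelial cells, with COL1A1 at 133 RPKM and 12 of 16 fibroblast and mural genes above day 8, 6 of 10 immediate early genes were higher than at day 8 and 0 were lower, with a median of 1.24. In HUVEC, 6 of 8 were higher than at day 8. JUN stood at 29.0 RPKM in the first library and 30.7 in HUVEC against 10.2 at day 8.

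The tests of a swap with day 8, of reads carried over and of mitochondrial ribosomal reads below were chosen only after the result was seen. The library labelled H1-derived endothelial cells held low endothelial and high fibroblast genes. A swap with HUVEC would only move the pattern to the HUVEC label and was not tested, and a swap with day 8 is excluded, since the correlation with day 4 differed by -0.24 from that of the library labelled day 8. Reads carried over from HUVEC are excluded as the source of the endothelial genes: 30% of 50 HUVEC genes lay under 0.5 times the endothelial median share, among them MGP at 0.173%. An earlier form of this test on 57 genes (77.2% under that limit), written before the result, was set aside because its choice of genes limits the share by itself. A minor share of endothelial cells among fibroblast-like cells may account for the pattern, as 69.0% of endothelial genes (20 of 29) lay within 2-fold of a median share of 5.85% of their HUVEC level (0.435% for VWF, 161% for FLT1), against 26% of the 50 HUVEC genes around their own median of 5.63%; a loss of endothelial genes in the cells themselves was not tested and stays open.

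A second pattern concerned 7 long genes that were high at days 2 and 8 and low at day 4: ANKRD30BL, NOTCH2NL, RP11-458D21.5 (which overlaps NOTCH2NL), HFM1, SLCO5A1, PDE3A and PID1. Reads of mitochondrial ribosomal RNA counted within these genes may account for it, since over the 2 libraries not used to find the pattern their median ratio of HUVEC to the library labelled H1-derived endothelial cells was 3.29, which is 0.835 times that of mitochondrial 16S ribosomal RNA (3.94). From day 2 to day 4 mitochondrial 16S ribosomal RNA fell 25.7-fold and 12S 38.6-fold. The 7 genes fell 35.9-fold to 69.2-fold, with a median of 1.26 times the 12S fall. A constant share of mitochondrial ribosomal reads as their whole level would give at most the 12S fall. ANKRD30BL, HFM1, SLCO5A1 and PDE3A lay above it, NOTCH2NL (40.7-fold) close to it, and PID1 and RP11-458D21.5 below it. Since the genes were found by this same fall, the comparison cannot exclude such a share. Reads of single stretches of these RNAs, which values per gene cannot show, and a true change of the genes stay open.

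Another pattern was that lncRNAs were more often lower than higher at day 2 against day 0: of the called genes 88.6% of lncRNAs and 53.3% of protein-coding genes were lower. With reads scaled to the library alone the contrast was smaller: 534 lncRNAs were lower and 117 higher, beside 1652 and 584 protein-coding genes. With TMM-like factors 61 protein-coding genes were lower and 148 higher. Counting error is excluded (0 lower lncRNAs in each of 20 draws of reads with no difference, against 62), and scaling is excluded as the whole cause (79.5% lower with TMM-like factors, 35 of 44). A trend with gene span is excluded as the whole cause within these 2 libraries. The median gap to protein-coding genes matched on level and span was -0.27 (-0.32 to -0.23 over 10000 resamples of the lncRNAs). It was -0.31 for 263 lncRNAs with no protein-coding gene on the same strand at the same place. The resampled genes are not replicates, so this range holds no variation between libraries. The gap was 0.04 and 0.03 at the next steps and -0.20, -0.37 and -0.27 for the library labelled H1-derived endothelial cells against day 8, day 0 and HUVEC. The ribosomal row RNA28S5 stood at 497 RPKM at day 2 against 4651 at day 0, while mitochondrial ribosomal RNA took 1.77% of reads against 0.393%. Whether a difference in how ribosomal RNA was removed or how the day 2 library was made bears on the lncRNAs could not be tested. The gene rows added up to 84.1% of reads at day 2, and a difference between the stages stays open.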
